A study of Rattus norvegicus with 9 samples.

How the data were processed

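RNA-seq libraries of neonatal rat cardiomyocytes were analysed, 9 in all, 3 each after infection with lenti-NC, lenti-TCF7L2 or lenti-shTCF7L2. Per the labels, cells came from newborn Sprague Dawley rats, were exposed to virus for 16 h and cultured for 48 h more. Per the labels, messenger RNA was selected with oligo(dT) beads and sequenced on a BGISEQ-500. Per the submitters' processing notes, HISAT2, Bowtie2, RSEM 1.3.1, DESeq2 1.4.5 and genome build rn6 were used; the notes give no roles or order. Groups were taken from the sample titles; the names of the files use GFP for lenti-NC and WT for lenti-TCF7L2, so whether the control vector carries GFP is not known. The authors deposited 1 table per library with expected counts per gene (estimated fragments, not normalised), FPKM values (fragments per kilobase of gene, scaled to library size) and gene lengths in bases, per the file headers.

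Between 84.2% and 84.5% of the expected counts in a library were whole numbers as printed. The files list only genes with a value above 0; 14607 genes were listed in any library and 12343 in all, and genes absent from a library were set to 0. For the 2264 genes absent from at least 1 library, the median of the highest count elsewhere was 2. No symbol was shared between identifiers.  A floor of 3 counts corresponds to 0.182 to 0.199 CPM per library. Floors and the intervals called counting intervals cover counting error only. The interval of the Car2 difference comes from the fit and includes spread between libraries. Genomic positions were not analysed here, since the reference annotation at hand is of another build than rn6. Mitochondrially encoded genes (39 in that list) were not listed in the files, and only 3 of 13 erythroid markers entered the tests, with 7 listed; these lists were not tested.

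Expected counts were rounded and genes were filtered with filterByExpr on the 3 groups, which kept 11761 and set aside 2846. Library sizes were scaled with TMM, and differences were tested with edgeR 4.0.16 (quasi-likelihood test, 2-sided) in R 4.3.3 with group as the only term and all 9 libraries in 1 fit. P-values were adjusted by the method of Benjamini and Hochberg over all genes tested, and an adjusted p under 0.05 was called a change. Unadjusted p under 0.05 held for 5185, 1889 and 5172 genes in lenti-TCF7L2 against lenti-NC, lenti-shTCF7L2 against lenti-NC, and lenti-TCF7L2 against lenti-shTCF7L2. Standard errors were derived from the log2 difference and the F statistic. The biological coefficient of variation was 14.9%. CPM values use TMM-scaled library sizes.

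The comparisons, the 30 gene lists, the other settings to be tried and the rule for naming genes were fixed before the data were examined. Lists with at least 5 tested genes (28) and annotation terms carried by the files with 10 to 300 tested genes (1084) were tested with camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists or terms of a comparison, and again with an estimated correlation. The lists cover sarcomere, calcium handling, cardiac transcription factors, fetal and hypertrophy, metabolism, Wnt, carbonic anhydrase, pH transport, stress, inflammation, interferon and proliferation genes, and markers of endothelial, fibroblast, epicardial, smooth muscle, macrophage, Schwann and erythroid cells. List medians per library are log2 CPM with a prior count of 2, against the mean of the lenti-NC libraries. Named genes were Tcf7l2 and Car2; the 10 largest rises and 10 largest falls per comparison among called genes whose groups did not overlap and whose higher group averaged at least 50 counts; and up to 3 members per list with the smallest adjusted p, or up to 2 by highest mean where none passed. Ratios against groups with 1 to 3 counts in all carry exact 95% binomial intervals.

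Alternatives were RLE and upper-quartile scaling, no filter, at least 10 counts in 6 libraries, DESeq2 1.42.0, limma-trend on log2 FPKM with a pseudocount of 1 or 0.1 (mean FPKM of at least 1, or no filter), a block for the replicate number, only the 6 libraries of the groups compared, no top 10 genes and Tcf7l2, each library left out in turn, and fry. A length adjustment (a lowess trend with a span of 0.3 on log2 length per library), alone and without lenti-TCF7L2 replicate 3, was chosen after seeing the data. Replicate numbers were checked for pairing: correlations of residuals between libraries of the same number ran from -0.067 to 0.151, with 2 of 9 over 0.1, so no block entered the comparisons. On simulated data with spread set wide, the procedure recovered 33.3%, 80.6% and 100% of genes changed by a log2 of 0.585, 1 and 2 in lenti-TCF7L2 against lenti-NC, and 28.8%, 79.1% and 97.0% in lenti-shTCF7L2 against lenti-NC, with 3.23% and 6.80% of calls false. With narrow spread these were 90.9%, 97.0% and 100%, and 87.9%, 100% and 100%, with 6.49% and 6.80% of calls false. Between the TCF7L2 viruses recovery was 45.5%, 82.0% and 98.5% with wide and 90.0%, 97.7% and 100% with narrow spread. There 4.29% and 7.78% of calls were false. All simulated libraries shared 1 spread per gene without a length trend, and 66, 67 and 67 genes per virus group were changed by those sizes. The data had unequal spread between groups and far more calls, so these rates need not hold for them. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.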

Results

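Messenger RNA was sequenced from primary cultures of neonatal rat cardiomyocytes, the contractile cells of newborn hearts, infected with 1 of 3 lentiviruses. Per the sample titles and labels, lenti-NC was the vector control, lenti-TCF7L2 carried TCF7L2 for overexpression, and lenti-shTCF7L2 carried a short hairpin RNA against it. TCF7L2 is a transcription factor that acts with β-catenin at the end of the canonical Wnt pathway. Each group held 3 libraries. The lenti-NC libraries held 15143338, 15146823 and 15259536 expected counts in all, the lenti-TCF7L2 libraries 15611407, 15478292 and 16478295, and the lenti-shTCF7L2 libraries 15150553, 15216193 and 15085922. Between 13294 and 13421 genes were listed per library, and 11761 genes entered the tests. Levels below are CPM (counts scaled to library size), mean ± SD, n = 3 libraries per group. The labels do not state that replicates are separate cultures, so the p-values rest on the spread between these samples. The fit took 1 spread per gene from all 9 libraries, so each comparison also draws on the group not compared. Replicates correlated less within lenti-TCF7L2 (lowest Pearson's r of log2 CPM 0.948) than within lenti-NC or lenti-shTCF7L2 (0.994 each). The p-values of lenti-shTCF7L2 against lenti-NC therefore do not measure the spread of those 6 libraries alone. In every gene named below as having risen or fallen, all 3 libraries of 1 group lay beyond all 3 libraries of the other. Counts of list members that rose or fell rest on the adjusted p and the direction alone.

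Tcf7l2 (Entrez gene 679869), the gene targeted by both viruses, stood at 36.8 ± 2.99 CPM with lenti-NC, 144 ± 60.1 with lenti-TCF7L2 and 27.3 ± 2.62 with lenti-shTCF7L2. Its expected counts were 595, 540 and 510 with lenti-NC, 2251, 3240 and 1434 with lenti-TCF7L2, and 388, 465 and 391 with lenti-shTCF7L2. Tcf7l2 rose by 1.97 on the log2 scale with lenti-TCF7L2 (SE 0.27, adjusted p = 8.46e-04). With lenti-shTCF7L2 its mean lay 25.9% below the control mean, and all 3 libraries lay below all 3 control libraries. That log2 difference of -0.43 (SE 0.27) did not pass the threshold in the fit of all 9 libraries (adjusted p = 0.511). It passed when only the 6 libraries of both groups were fitted (adjusted p = 1.81e-04) and when lenti-TCF7L2 replicate 3 was left out (-0.45, adjusted p = 0.0285). Over the tested alternatives its adjusted p ran from 1.81e-04 to 0.770. The labels do not give the species of the TCF7L2 insert, so which of its reads were counted under the rat gene is not known.

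Car2 (Entrez gene 54231), carbonic anhydrase 2, is the gene named in the study title as lying downstream of TCF7L2. Its counts were low: 29, 17 and 25 with lenti-NC, 31, 29 and 41 with lenti-TCF7L2, and 20, 16 and 27 with lenti-shTCF7L2. The log2 difference from lenti-NC was 0.39 with lenti-TCF7L2 (95% interval -0.20 to 0.98, adjusted p = 0.280) and -0.20 with lenti-shTCF7L2 (SE 0.28, adjusted p = 0.851). Between the TCF7L2 viruses it was 0.59 (SE 0.27, adjusted p = 0.122). With lenti-TCF7L2 the Car2 difference was 0.20 without lenti-NC replicate 2 and 0.24 without lenti-TCF7L2 replicate 3. With lenti-shTCF7L2 it was -0.03 without lenti-NC replicate 1, -0.39 without lenti-NC replicate 2, -0.03 without lenti-shTCF7L2 replicate 2 and -0.43 without lenti-shTCF7L2 replicate 3. No difference in Car2 was detected. Among 12 tested carbonic anhydrase genes, 4 rose and 1 fell with lenti-TCF7L2, the same counts when adjusted over the list alone. Car4, a membrane-anchored isoform, rose by 2.07 (SE 0.39, adjusted p = 0.00433). Car11 rose by 0.94 (adjusted p = 4.77e-04), and Car14 changed by -1.01 (adjusted p = 1.28e-04). The list as a whole did not pass (median log2 difference 0.32, adjusted p = 0.537). With lenti-shTCF7L2, 0 of the 12 passed in edgeR, where 2 lower and 0 higher had an unadjusted p under 0.05. In DESeq2 1 passed, which was lower.

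**Figure D1:**
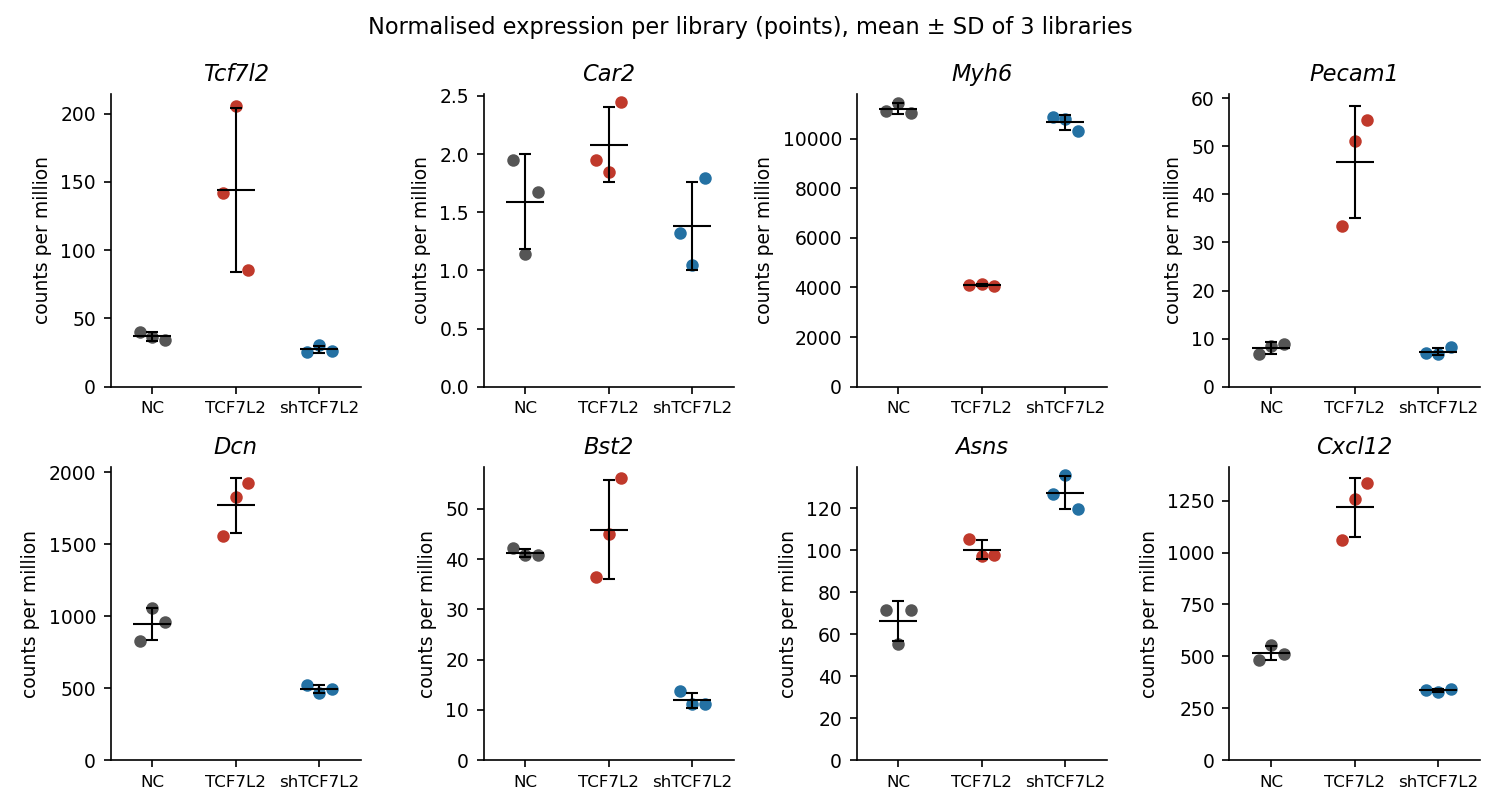
Normalised expression (CPM, linear axis from 0) of 8 genes in each library; points are libraries, horizontal marks are group means and bars are SD, n = 3. Tcf7l2 is highest in the 3 lenti-TCF7L2 libraries, Myh6 is lowest in them, with a mean of 4099 CPM, and Dcn lies in opposite directions from lenti-NC with the TCF7L2 viruses.

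The comparison of lenti-TCF7L2 with lenti-NC asks how raised TCF7L2 changes the transcriptome. The sarcomere list was lower with lenti-TCF7L2, and the endothelial, inflammation, and macrophage and leukocyte lists were higher; these calls held with an estimated correlation. Myh6, the α-myosin heavy chain of cardiac muscle, fell from 11201 ± 221 to 4099 ± 46.1 CPM (log2 difference -1.45, SE 0.08, adjusted p = 2.41e-05). Mb, the oxygen-binding myoglobin, fell from 121 ± 11.1 to 24.1 ± 4.60 CPM (-2.33, SE 0.14). Pecam1, an adhesion molecule of endothelial cells, rose from 8.06 ± 1.16 to 46.7 ± 11.7 CPM (2.54, SE 0.20). Cxcl12, a chemokine, rose from 516 ± 35.2 to 1219 ± 142 CPM (1.24, SE 0.10).

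Among the genes with the largest rises, Cldn5 (3.55), Dll4 (3.53), Sox18 (3.46) and Emcn (3.20) are endothelial genes. Cldn5 forms endothelial tight junctions, Dll4 is a Notch ligand and Sox18 is a transcription factor of vessels. Fam110d (3.97), Lrg1 (3.28), the protease inhibitor Slpi (3.17) and the potassium channel subunit Kcne3 (3.04) also rose. Aoc1, a diamine oxidase, rose by 4.43 from 2, 3 and 5 counts to 58, 87 and 97. Rnase1l2 had 0, 1 and 0 counts with lenti-NC and 40, 40 and 71 with lenti-TCF7L2, a ratio of 140 (95% counting interval 24.7 to 5546). The largest falls were in Astn2 (-2.77), the myosin light chain Myl1 (-2.75), the nuclear receptor Esrrb (-2.46), Atp12a (-2.44), the fatty acid desaturase Scd (-2.43), Asb11 (-2.34), Gpr22 (-2.28), Asb4 (-2.26) and Myom2 (-2.18), a protein of the sarcomere's M band.

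Of 29 tested sarcomere genes, 24 fell and 1 rose (median -0.92, adjusted p = 1.52e-24 for the list), 25 lower and 1 higher when adjusted over the list alone. Besides Myh6, Myom1 (-1.07) and the myosin-binding protein Mybpc3 (-0.93) fell. Of 42 genes of calcium handling and ion channels, 27 fell and 3 rose (median -0.74), 30 and 3 when adjusted over the list alone. That list's call was lost at an adjusted p = 0.0636 with an estimated correlation. The calcium-binding proteins of the sarcoplasmic reticulum Casq2 (-1.04) and Casq1 (-1.32) fell, as did Trdn (-1.20), which anchors them. Of 21 fetal and hypertrophy genes, 14 fell and 2 rose (median -0.51), 15 and 3 when adjusted over the list alone. Myh7, the slow myosin heavy chain, fell by 1.04, and Fhl1 (-1.12) and the skeletal actin Acta1 (-1.28) fell too. Among 21 cardiac transcription factors, 13 fell and 1 rose (median -0.76), 14 and 1 when adjusted over the list alone (adjusted p = 0.247 with an estimated correlation). Irx3 changed by -1.02 and Irx5 by -0.99.

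Of 36 oxidative phosphorylation genes encoded in the nucleus, 23 fell (median -0.45), 24 when adjusted over the list alone (adjusted p = 0.392 with an estimated correlation). They included Ndufs1 of complex I (-1.02), Sdha of complex II (-0.83) and Uqcrc2 of complex III (-0.78). Glycolysis and glucose genes had 11 of 27 members lower (median -0.35), 13 lower and 1 higher when adjusted over the list alone (adjusted p = 0.186 with an estimated correlation). Slc2a4, the insulin-responsive glucose transporter, changed by -1.81, Pdha1 of pyruvate dehydrogenase by -1.01 and Pfkm by -0.72. Of 31 fatty acid oxidation genes, 14 fell and 5 rose (median -0.24), 16 and 5 when adjusted over the list alone (adjusted p = 0.432 with an estimated correlation). The fatty acid transporter Cd36 (-1.20) and Acsl1 (-1.06) fell, while Angptl4, a lipase inhibitor, rose by 2.28. Without lenti-TCF7L2 replicate 3 the median of the fatty acid oxidation list was -0.41. Of 23 cholesterol synthesis genes, 9 fell and 1 rose (median -0.26), 10 and 1 when adjusted over the list alone (adjusted p = 0.392 with an estimated correlation). The cholesterol list's median was -0.15 without lenti-NC replicate 1 and -0.17 without lenti-TCF7L2 replicate 2. Insig1 and Hmgcs1 each changed by -0.64. Among 21 pH and bicarbonate transport genes, 6 fell and 1 rose (median -0.36), 7 and 1 when adjusted over the list alone (adjusted p = 0.355 with an estimated correlation). Aqp1 (-0.96), the anion exchanger Slc4a3 (-0.93) and the lactate transporter Slc16a1 (-0.89) fell, and the list's median was -0.62 without lenti-TCF7L2 replicate 2.

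Of 22 endothelial markers, 17 rose and 2 fell (median 1.71, adjusted p = 7.46e-13), 17 and 3 when adjusted over the list alone. Tie1 (2.17), Emcn and Pecam1 had the smallest adjusted p values. The receptors for vascular endothelial growth factor Kdr (-0.50, adjusted p = 0.0722) and Flt1 (-0.05, adjusted p = 0.805), picked after their values were seen, did not pass. Of 30 inflammation genes, 21 rose (median 0.79), 23 when adjusted over the list alone, with Cxcl6 (1.68), Cxcl12 (1.24) and the alarmin Il33 (1.31) first by p. Of 14 tested macrophage and leukocyte markers, 8 rose (median 0.76), 11 when adjusted over the list alone. Fcer1g rose by 1.43, Cd68 by 1.17 and Cd14 by 0.82. Of 38 interferon response genes, 8 rose (median 0.46), 7 when adjusted over the list alone (adjusted p = 0.567 with an estimated correlation). Ifitm3 rose by 1.05, Ifitm1 by 1.04 and Psmb9 by 0.93, and the list's median was 0.27 without lenti-TCF7L2 replicate 2. The 3 lenti-TCF7L2 libraries had interferon list medians of -0.02, 0.85 and 0.51 against the control mean.

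Of 29 fibroblast and matrix markers, 12 rose and 3 fell (median 0.16), 13 and 3 when adjusted over the list alone (adjusted p = 0.392 with an estimated correlation). The small matrix proteoglycans Fmod (1.39), Lum (0.98) and Dcn (0.90) rose. The fibroblast list's call was lost without lenti-TCF7L2 replicate 1 (median 0.11, adjusted p = 0.0525). Its median was 0.09 without lenti-TCF7L2 replicate 2 and 0.27 without lenti-TCF7L2 replicate 3. Of 33 ribosomal protein genes, 13 rose (median 0.47), 26 when adjusted over the list alone (adjusted p = 0.567 with an estimated correlation). These genes are short, and the list's median was 0.22 without lenti-TCF7L2 replicate 3.

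Another 3 lists were called at an adjusted p just under the threshold. ER stress and integrated stress genes had 12 of 29 higher and 1 lower (median 0.23, adjusted p = 0.0422), the same counts when adjusted over the list alone (adjusted p = 0.392 with an estimated correlation). Phgdh (0.61) and Psat1 (0.72), enzymes of serine synthesis, rose, and the chaperone Canx changed by -0.45. Immediate early and heat shock genes had 9 of 23 higher and 2 lower (median 0.18), the same when adjusted over the list alone (adjusted p = 0.171 with an estimated correlation). Nr4a1 (0.87), Ier2 (0.84) and Junb (0.67) rose. Proliferation genes had 9 of 37 higher (median 0.17), 8 when adjusted over the list alone (adjusted p = 0.567 with an estimated correlation), including Cdt1 (0.67), Mcm6 (0.54) and Mcm5 (0.39) of DNA replication licensing. The ER stress call was lost without lenti-NC replicate 2 (adjusted p = 0.0897), lenti-TCF7L2 replicate 1 (0.0649) or 3 (0.0952, median 0.13), or lenti-shTCF7L2 replicate 1 (0.0518), 2 (0.0517) or 3 (0.0539). The immediate early call was lost without lenti-NC replicate 3 (adjusted p = 0.0549) or lenti-TCF7L2 replicate 1 (0.0649) or 2 (0.0582). The proliferation call was lost without lenti-NC replicate 2 (adjusted p = 0.156) or 3 (0.0855), lenti-TCF7L2 replicate 1 (0.0745) or 2 (0.139), or lenti-shTCF7L2 replicate 1 (0.0534), 2 (0.0517) or 3 (0.0561).

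Of 22 Wnt target genes, 4 rose and 4 fell (median 0.11, adjusted p = 0.877), 4 and 4 when adjusted over the list alone. Myc (0.88), Fosl1 (0.67) and the adhesion receptor Cd44 (0.47) rose, but Myc and Cd44 were also called higher with lenti-shTCF7L2. Axin2, a widely used readout of the pathway picked here after its value was seen, differed by 0.15 (SE 0.24, adjusted p = 0.655). Of 50 Wnt pathway components, 11 rose and 9 fell (median -0.10, adjusted p = 0.644), 14 and 9 when adjusted over the list alone, with the receptor Fzd6 (-0.76) and the secretion factor Wls (-0.57) lower and the antagonist Frzb (1.06) higher. The remaining lists did not pass and had medians of -0.12 (insulin and diabetes), 0.12 (oxidative stress), -0.13 (p53 and apoptosis), -0.05 (epicardial), -0.06 (smooth muscle and pericyte), -0.18 (TGF-β response) and 0.18 (Schwann and neural). Individual members of those lists changed, among them Igfbp4 (1.86), Igfbp3 (1.09), Hmox1 (0.82), Mt2A (1.97), Ccng1 (-1.15), Aldh1a2 (1.18), Kcnj8 (1.15) and Id3 (0.89). For the Wnt target and the Schwann and neural lists the test pointed up and the median was positive while the mean was -0.01 and -0.00. Lenti-TCF7L2 replicates 1, 2 and 3 had TGF-β list medians of 0.004, -0.01 and -0.37 against the control mean. For insulin and diabetes these were -0.08, 0.09 and -0.62. They were -0.04, 0.10 and -0.34 for Wnt components and 0.08, 0.16 and -0.20 for Wnt targets.

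**Figure D2:**
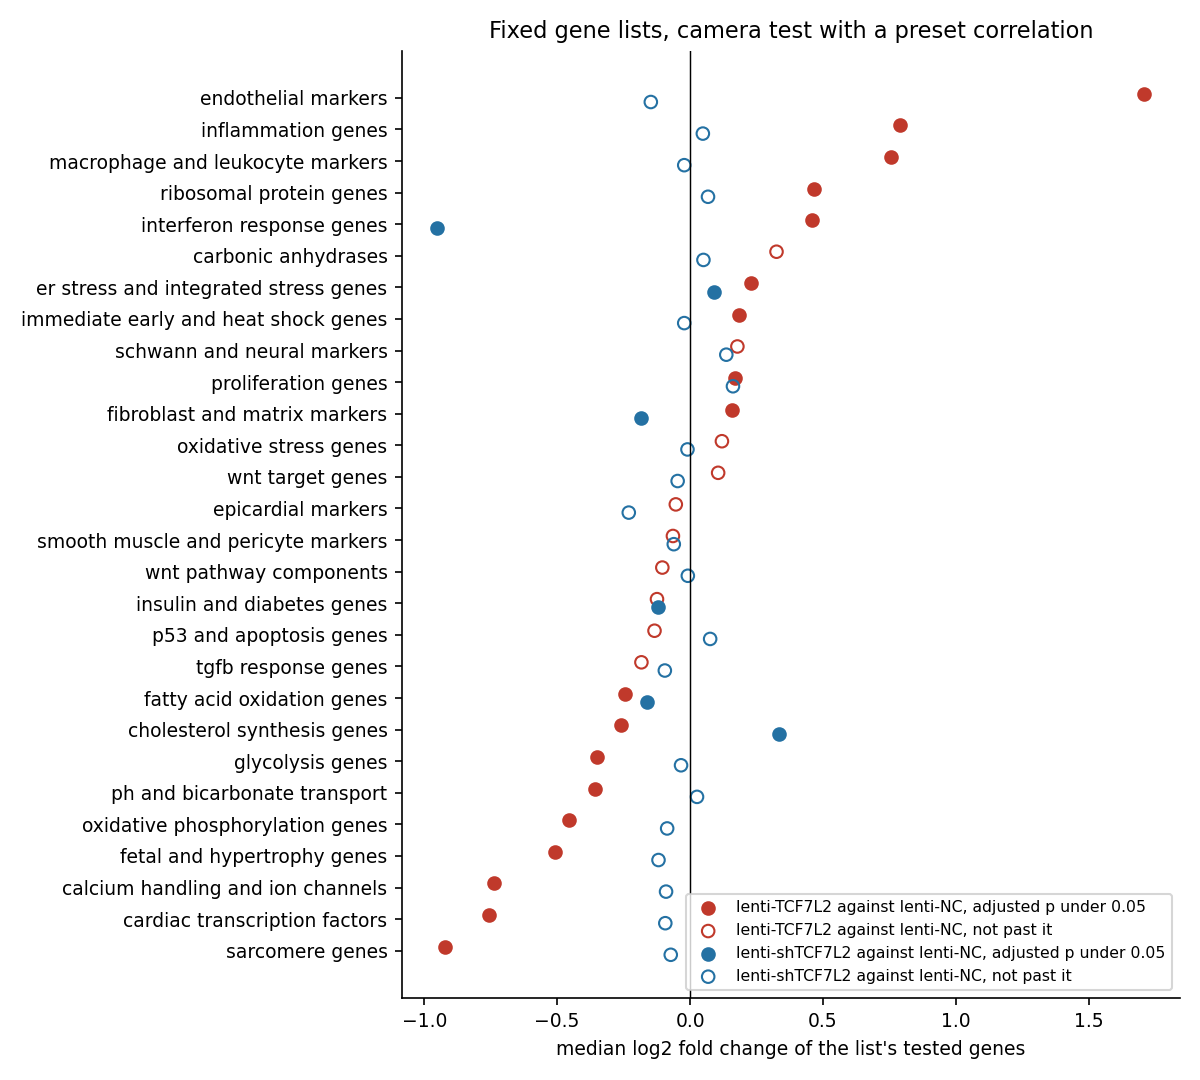
Median log2 difference from lenti-NC of the tested genes of each of 28 fixed lists (horizontal axis), for lenti-TCF7L2 (red) and lenti-shTCF7L2 (blue); filled circles passed an adjusted p of 0.05 in camera with a preset correlation. Endothelial markers lie highest with lenti-TCF7L2 at 1.71 and sarcomere genes lowest at -0.92, while interferon response genes lie lowest with lenti-shTCF7L2 at -0.95.

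In total 3738 of 11761 genes changed with lenti-TCF7L2, 2116 higher and 1622 lower, of which 398 and 381 by at least 2-fold. The groups did not overlap in 46.8% of tested genes, against 10% by chance. Of 28 lists, 18 passed camera, and 5 held with an estimated correlation: sarcomere and inflammation (adjusted p = 0.0267 each), and endothelial, fetal and hypertrophy, and macrophage and leukocyte (0.0271 each). Of 1084 annotation terms, 24 were higher and 36 lower, led by cytokine activity (15 of 23 genes higher, median 0.87) and aerobic respiration (18 of 21 lower, median -0.62). The lowest adjusted p of any term was 0.213 with an estimated correlation. The count of changed genes was 2430, 2458 and 2486 without lenti-NC replicate 1, 2 and 3, and 2321 with only the 6 libraries of both groups. Lenti-TCF7L2 replicate 3 stood apart from replicates 1 and 2: its genes of over 8000 bases had a median of -1.09 against the control mean and those of up to 1000 bases 0.54.

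**Figure D3:**
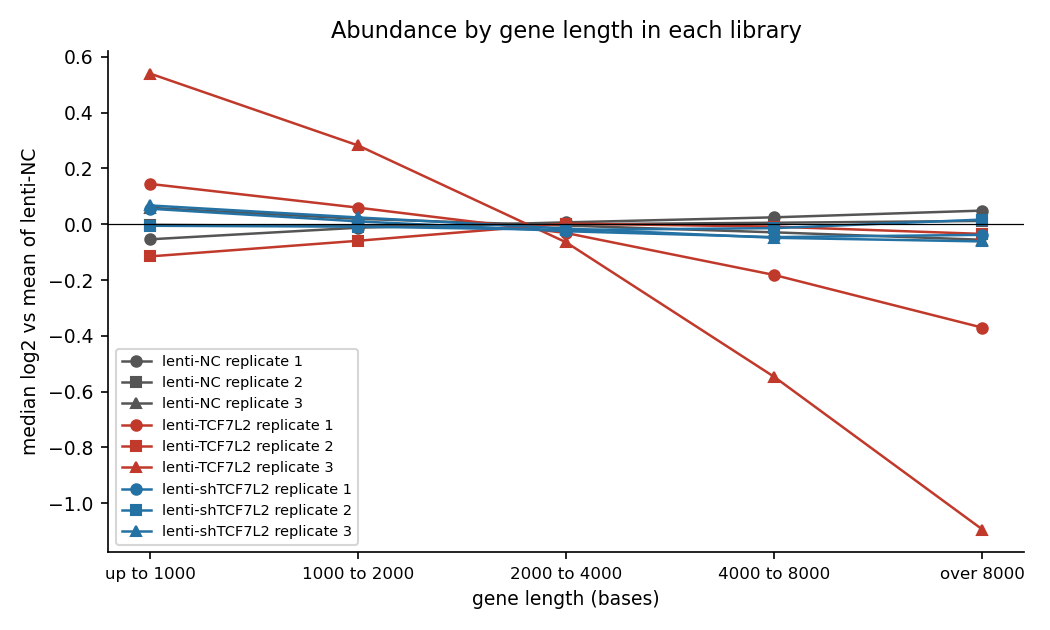
Median log2 difference from the mean of the lenti-NC libraries for genes grouped by length in bases, 1 line per library. Lenti-TCF7L2 replicate 3 runs from 0.54 for the shortest to -1.09 for the longest genes, and lenti-TCF7L2 replicate 1 from 0.14 to -0.37.

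The comparison of lenti-shTCF7L2 with lenti-NC asks what the hairpin against TCF7L2 does. The interferon response and the fibroblast and matrix lists were lower with lenti-shTCF7L2, and the cholesterol synthesis list was higher. None of these calls held with an estimated correlation (adjusted p = 0.155, 0.155 and 0.165). That correlation was estimated from all 9 libraries, so it also draws on the lenti-TCF7L2 replicates, which correlated least. Bst2, an antiviral membrane protein induced by interferon, fell from 41.3 ± 0.777 to 11.9 ± 1.49 CPM (log2 difference -1.79, SE 0.16, adjusted p = 0.00123). C6, a complement component, fell from 22.9 ± 2.96 to 7.18 ± 0.636 CPM (-1.67, SE 0.14). Dcn fell from 947 ± 114 to 494 ± 27.7 CPM (-0.94, SE 0.11). Asns, asparagine synthetase, rose from 66.2 ± 9.47 to 127 ± 7.98 CPM (0.94, SE 0.11, adjusted p = 0.00312).

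Among genes averaging at least 50 counts in the higher group, the largest falls that passed with every library left out in turn were Cxcl10 (-1.97), Serpina3n (-1.91), Bst2, Chi3l1 (-1.78), Oasl (-1.70), C6 and complement factor B, Cfb (-1.61). The largest such rises, under the same limit, were Cd55 (1.77), an inhibitor of complement on cell surfaces, Adm2 (1.64) and the cationic amino acid transporter Slc7a3 (2.84-fold). Gja5, the gap junction protein connexin 40, also fell under each of these fits, by 1.07. Of 65 calls of named genes in this comparison, 19 passed in all 9 fits with 1 library left out and 46 did not in at least 1. Among the latter were complement C4a (-2.08) and the chemokine Ccl12 (1.27), each with an adjusted p of 0.0509 without lenti-shTCF7L2 replicate 3 and under 0.05 in the other 8 fits.

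Of 38 interferon response genes, 14 fell (median -0.95, adjusted p = 3.67e-38), 32 when adjusted over the list alone (adjusted p = 0.155 with an estimated correlation). The 3 lenti-shTCF7L2 libraries had list medians of -0.74, -1.07 and -0.92 against the control mean. Besides Bst2, the guanylate-binding protein Gbp2 (from 20.9 ± 2.22 to 10.5 ± 0.282 CPM) and Ifi27 (-0.95) fell. Of 29 fibroblast and matrix markers, 7 fell (median -0.18), 11 lower and 1 higher when adjusted over the list alone (adjusted p = 0.155 with an estimated correlation). They included Fmod (-1.32), Dcn and the fibroblast transcription factor Tcf21 (-1.01). Of 23 cholesterol synthesis genes, 4 rose (median 0.33), 10 when adjusted over the list alone (adjusted p = 0.165 with an estimated correlation). Of 29 ER stress and integrated stress genes, 6 rose (median 0.09), 7 when adjusted over the list alone (adjusted p = 0.155 with an estimated correlation). Asns and Phgdh (0.86) were among them, both enzymes of amino acid synthesis, and this list's median was 0.14 without lenti-NC replicate 1.

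Of 26 insulin and diabetes genes, 4 fell and 1 rose (median -0.12, adjusted p = 0.0168), 4 and 1 when adjusted over the list alone (adjusted p = 0.934 with an estimated correlation). Fatty acid oxidation genes had a median of -0.16 (adjusted p = 0.00933 for the list; adjusted p = 0.934 with an estimated correlation). Of its 31 members 0 passed in edgeR, also when adjusted over the list alone; 1 higher and 6 lower had an unadjusted p under 0.05, and 2 passed in DESeq2. That list's call was lost without lenti-shTCF7L2 replicate 2 (adjusted p = 0.0609). The other 22 lists did not pass and had medians from -0.23 (epicardial) to 0.16 (proliferation), with sarcomere at -0.07, endothelial at -0.15, Wnt targets at -0.05 and Wnt components at -0.01. Among Wnt components, the receptor Fzd1 fell by 0.69 (adjusted p = 0.00450) and passed in all 9 fits with 1 library left out. The median was positive and the test pointed down for carbonic anhydrases, inflammation, and pH and bicarbonate transport. The median was negative and the test pointed up for fetal and hypertrophy, glycolysis, immediate early, macrophage, oxidative stress and smooth muscle lists, none of which passed.

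In total 428 genes changed with lenti-shTCF7L2, 155 higher and 273 lower, of which 25 and 65 by at least 2-fold, and 1889 had an unadjusted p under 0.05. The groups did not overlap in 40.9% of genes, against 10% by chance. Among 1084 terms, 5 were higher and 21 lower, led by the MHC protein complex (11 of 41 genes lower, median -0.51), with the lowest adjusted p of any term at 0.999 with an estimated correlation. The count varied with the libraries fitted and the tool: it was 3294 with only the 6 libraries of both groups, 2056 without lenti-TCF7L2 replicate 3, 643 without lenti-TCF7L2 replicate 2 and 651 in DESeq2. It was 180, 103 and 105 without lenti-NC replicate 1, 2 and 3, and 144, 88 and 91 without lenti-shTCF7L2 replicate 1, 2 and 3. All 428 genes were among those called in the fit of 6 libraries.

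**Figure D4:**
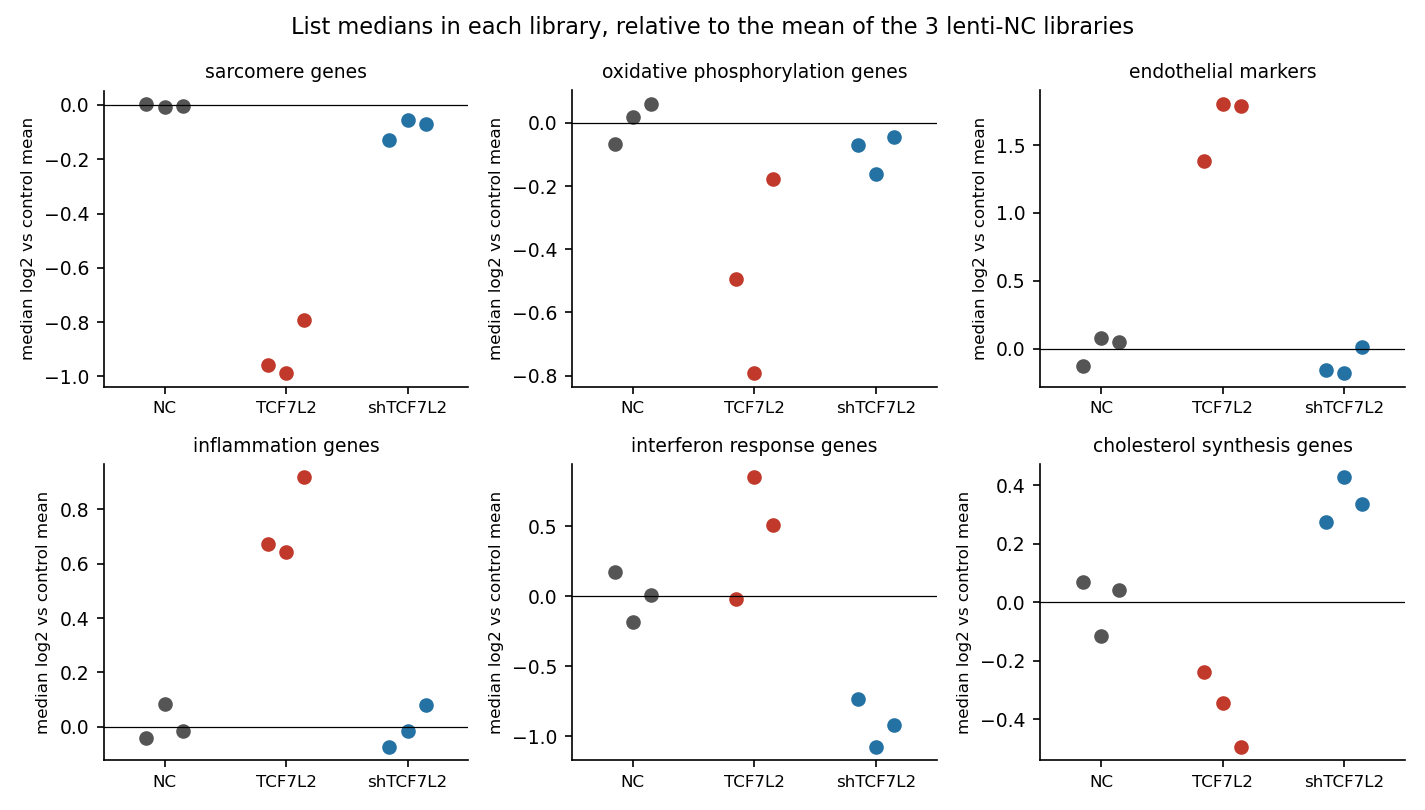
Median log2 difference from the mean of the 3 lenti-NC libraries for 6 gene lists, 1 point per library; vertical scales differ between panels. Sarcomere medians of the lenti-TCF7L2 libraries lie between -0.99 and -0.79, and interferon medians of the lenti-shTCF7L2 libraries between -1.07 and -0.74.

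The direct comparison of lenti-TCF7L2 with lenti-shTCF7L2 sets the overexpression virus against the hairpin virus; the lenti-NC libraries were also in the fit, which held all 9. The endothelial and inflammation lists were higher with lenti-TCF7L2 and the sarcomere list was lower, and these calls held with an estimated correlation. The interferon and the fibroblast and matrix lists were also higher and the cholesterol synthesis list lower, but these calls did not hold (adjusted p = 0.164, 0.0746 and 0.118 with an estimated correlation). Cfb stood at 86.6 ± 17.6 CPM with lenti-TCF7L2 and 7.29 ± 1.11 with lenti-shTCF7L2 (log2 difference 3.57, SE 0.20, adjusted p = 1.52e-05). Acta1 stood at 160 ± 21.5 and 662 ± 32.5 CPM (-2.04, SE 0.11, adjusted p = 1.44e-05). Fmod differed by 2.71, Dcn by 1.84 and Tcf21 by 1.49.

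Large differences upward were also seen in Slpi (3.98), Fam110d (3.85), Car4 (3.83), Kcne3 (3.63), Elf5 (3.62) and Dll4 (3.53). Another 3 genes had almost no counts with lenti-shTCF7L2. Aoc1 had 242 counts in all with lenti-TCF7L2 and 1 with lenti-shTCF7L2, a ratio of 228 (95% counting interval 40.5 to 9044). Rnase1l2 had 151 and 2 (71.1, interval 19.4 to 593), and Lrg1 had 151 and 3 (47.4, interval 15.9 to 233). Large differences downward were seen in the lipid genes Scd (-3.18) and Pnpla3 (-2.49), in Mb (-2.74) and Myl1 (-2.55), and in Smim5 (-2.89), Fcer2 (-2.82), Esrrb (-2.66), Astn2 (-2.59) and Atp12a (-2.48).

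Of 38 interferon response genes, 35 were higher with lenti-TCF7L2 (median 1.39), 37 when adjusted over the list alone (adjusted p = 0.164 with an estimated correlation), among them Oasl (27.9 ± 6.43 against 4.92 ± 0.805 CPM), Ifitm1 (1.88) and Gbp2 (1.43). Of 23 cholesterol synthesis genes, 19 were lower (median -0.66), 20 when adjusted over the list alone (adjusted p = 0.118 with an estimated correlation), among them Sc5d (-1.06), Insig1 (-0.96) and Idi1 (23.6 ± 0.856 against 47.5 ± 4.72 CPM). Of 29 fibroblast and matrix markers, 12 were higher and 1 lower (median 0.28), 14 and 1 when adjusted over the list alone (adjusted p = 0.0746 with an estimated correlation). Sarcomere genes had 23 of 29 lower and 1 higher (median -0.82), 24 and 1 when adjusted over the list alone. Endothelial markers had 17 of 22 higher and 1 lower (median 1.74), 17 and 2 when adjusted over the list alone, led by Pecam1 (2.68), Plvap (2.56) and Emcn (3.47). Inflammation genes had 21 of 30 higher and 1 lower (median 0.88), 22 and 1 when adjusted over the list alone, led by Cxcl12 (1.86), Cxcl6 (1.44) and Mmp9 (2.57). Macrophage and leukocyte markers had 8 of 14 higher and 1 lower (median 0.81), and fetal and hypertrophy genes had 10 of 21 lower and 2 higher (median -0.48), 8 and 1, and 12 and 2 when adjusted over the list alone. Of 28 lists, 14 passed, and 5 held with an estimated correlation: sarcomere, endothelial, inflammation, macrophage and leukocyte, and fetal and hypertrophy (adjusted p = 0.0368 each).

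The other called lists did not hold with an estimated correlation. The median was -0.71 for calcium handling genes (adjusted p = 0.118 with an estimated correlation), -0.83 for cardiac transcription factors (0.262) and -0.31 for glycolysis genes (0.164). For oxidative phosphorylation genes the median was -0.39 (adjusted p = 0.557 with an estimated correlation), for pH and bicarbonate transport -0.29 (0.332) and for ribosomal proteins 0.41 (0.755). Without lenti-TCF7L2 replicate 3 the median was -0.52 for cardiac transcription factors and 0.19 for ribosomal proteins. The pH and bicarbonate median was -0.48 without lenti-TCF7L2 replicate 2 and -0.45 without lenti-shTCF7L2 replicate 2. The other 14 lists did not pass and had medians from -0.19 (Schwann and neural) to 0.16 (carbonic anhydrases). The insulin and diabetes and the oxidative stress lists had negative medians and positive means, with the test pointing up; Wnt components had a negative median and a positive mean, with the test pointing down. In total 3890 genes differed (2644 with only the 6 libraries of both groups), 2161 higher and 1729 lower with lenti-TCF7L2, of which 604 and 365 by at least 2-fold, and the groups did not overlap in 47.2% of genes against 10% by chance. Among 1084 terms, 42 were higher and 30 lower, led by cytokine activity, and the lowest adjusted p of any term was 0.249 with an estimated correlation.

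Some genes were called against lenti-NC with both viruses. There were 112 genes higher with lenti-TCF7L2 and lower with lenti-shTCF7L2. Of these, 29 were called with both viruses in all 9 fits with 1 library left out, and the genes named next are among them. Cfb went from 22.2 ± 3.60 CPM with lenti-NC to 86.6 ± 17.6 with lenti-TCF7L2 and 7.29 ± 1.11 with lenti-shTCF7L2. Other complement genes, a grouping made after the values were seen and not tested as a list, were C6 (0.88 and -1.67), C1r (0.52 and -0.58), C1s (0.51 and -1.04) and the complement inhibitor Serping1 (1.18 and -1.46). Matrix genes were Fmod (1.39 and -1.32), Fbln1 (1.32 and -1.32) and Dcn (0.90 and -0.94). Agtr1a (0.77 and -0.88), a receptor for angiotensin II, Il1rl1 (0.53 and -1.04), the receptor of Il33, Tcf21 (0.49 and -1.01) and Gja5 (0.54 and -1.07) showed the pattern too. In the reverse pattern there were 20 genes, against 21.4 if the calls were independent, and 0 of them passed in all 9 edgeR fits. Shared controls make the calls dependent, so 21.4 is no measure of chance here. Acta1 (-1.28 and 0.76) had the reverse pattern, with an adjusted p for lenti-shTCF7L2 of 0.0502 without lenti-NC replicate 2, 0.0501 without lenti-NC replicate 3 and 0.0542 without lenti-shTCF7L2 replicate 2. By list, 6 fibroblast and matrix markers and 4 interferon response genes were higher with lenti-TCF7L2 and lower with lenti-shTCF7L2.

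Genes also moved the same way with both viruses. There were 70 genes higher with both and 60 lower with both; 9 and 15 of them were called in all 9 fits with 1 library left out. Among the 9 were the amino acid genes Asns (0.60 and 0.94), Phgdh (0.61 and 0.86) and Slc6a9 (0.44 and 0.56), a glycine transporter, and the hormone Adm2 (1.19 and 1.64). Among the 15 were Jup (-0.50 and -0.51), the plakoglobin of cell junctions, the circadian repressor Nr1d1 (-0.43 and -0.62), the mitochondrial cyclophilin Ppif (-0.81 and -0.71) and the sphingosine receptor S1pr1 (-0.83 and -0.57). By list, 5 ER stress and integrated stress genes were higher with both. Of the Wnt targets, 2 were higher with both, 1 was lower with both and 0 were called in opposite directions. The 2 were Myc (0.88 and 0.47) and Cd44 (0.47 and 0.43), neither called with both viruses in all 9 fits. Except for the list members named by rule, the genes of both overlaps were picked after their values were seen.

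Both comparisons share the 3 lenti-NC libraries, which alone makes their log2 differences vary together. Across the 11761 genes, which are not independent replicates, Pearson's r of the differences was 0.061 and Spearman's rho 0.151. In 100 simulations of 3 unchanged groups with shared controls r averaged 0.383 (range 0.338 to 0.441) and rho 0.318 (range 0.292 to 0.340). The covariance of the differences was 0.0109, against 0.0111 in the simulations (range 0.00954 to 0.0136), so the lower r came with larger variances and does not show the responses pulling apart. If the calls were independent, 49.1 genes would be higher with lenti-TCF7L2 and lower with lenti-shTCF7L2 (112 were), 21.4 the reverse (20 were), 27.9 higher with both (70 were) and 37.7 lower with both (60 were). The shared controls make the calls dependent, so these numbers are not what unchanged groups would give. Calls in opposite directions numbered 132 and in the same direction 130. The opposite count was 62, 36 and 36 without lenti-NC replicate 1, 2 and 3, 493 without lenti-TCF7L2 replicate 3, and 55, 33 and 33 without lenti-shTCF7L2 replicate 1, 2 and 3. The same-direction count was 48, 28 and 31 without lenti-NC replicate 1, 2 and 3, 84, 228 and 737 without lenti-TCF7L2 replicate 1, 2 and 3, and 40, 30 and 30 without lenti-shTCF7L2 replicate 1, 2 and 3.

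**Figure D5:**
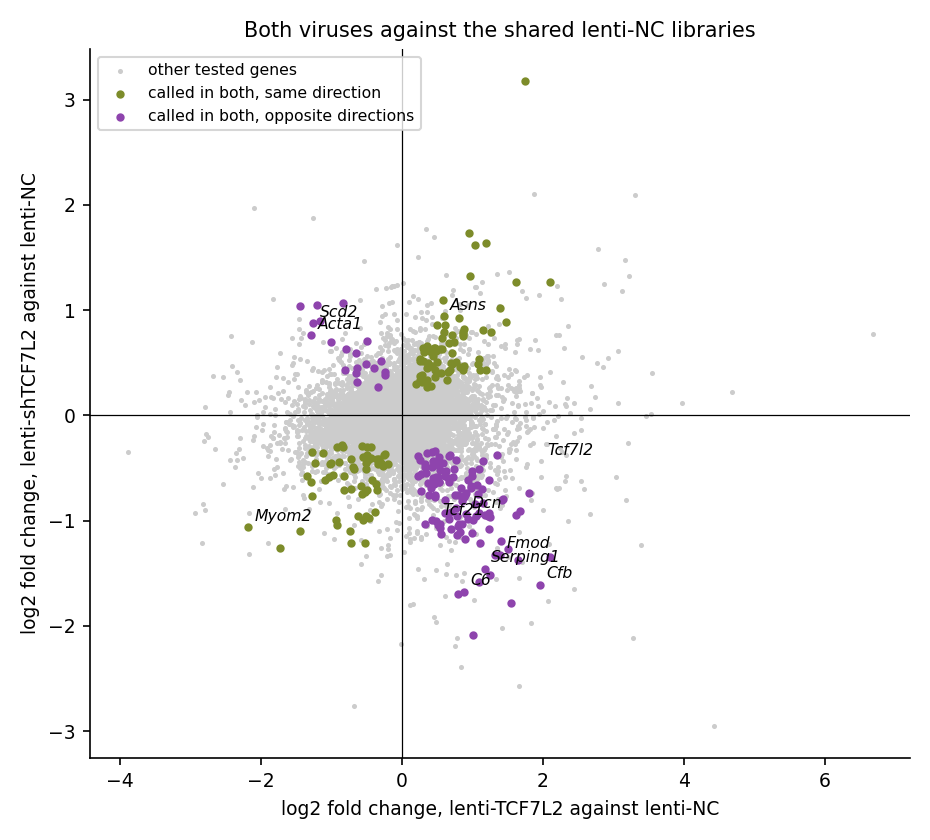
Log2 difference from lenti-NC with lenti-TCF7L2 (horizontal axis) and lenti-shTCF7L2 (vertical axis) for 11761 genes; purple points were called with both viruses in opposite directions and green points in the same direction. Below and to the right lie 112 called genes, among them Cfb, C6, Serping1, Fmod and Dcn.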

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

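The length adjustment, alone or without lenti-TCF7L2 replicate 3, was chosen only after the results were seen; the other alternatives were planned. No result reversed. Of 6055 values of named genes under the alternatives, 5709 kept their direction and side of the threshold, 324 lost and 22 gained a call; of 1926 list values these were 1832, 62 and 32. Scaling, filters and limma on FPKM left the counts of changed genes within 1.5 times. Genes changed with lenti-shTCF7L2 against lenti-NC (428) numbered 651 in DESeq2, 244 with a replicate block, 3294 with only the 6 libraries compared, 1089 after length adjustment and 2669 with that library also left out. Genes changed with lenti-TCF7L2 against lenti-NC (3738) numbered 2321 with only 6 libraries and 5632 after length adjustment without that library, and those between the TCF7L2 viruses (3890) then numbered 5935. Calls with both viruses in opposite directions (132) numbered 86 with a block, 369 with 6 libraries, 304 after length adjustment and 684 with that library also left out. Those in the same direction (130) numbered 203 in DESeq2, 73, 576, 419 and 1035. Their split into higher and lower with both, 70 and 60, was 95 and 108 in DESeq2. It was 113 and 52 in limma on log2(FPKM + 1). Tcf7l2 with lenti-shTCF7L2 passed at -0.43 with only 6 libraries (adjusted p = 1.81e-04) and at -0.42 after length adjustment without that library (adjusted p = 0.0125); its adjusted p ran from 1.81e-04 to 0.770 over all alternatives. With an estimated correlation 5, 0 and 5 lists passed camera in place of 18, 6 and 14. In lenti-shTCF7L2 against lenti-NC 4 lists then had an unadjusted p under 0.05. In that comparison 5 lists passed fry. Of these, camera had also called fibroblast and matrix (fry adjusted p = 0.0147), ER stress (0.0147), cholesterol synthesis (0.0158) and interferon (0.0225). It had not called p53 and apoptosis (0.0278). Fatty acid oxidation (adjusted p = 0.231) and insulin and diabetes (0.368), called by camera, did not pass fry. With lenti-TCF7L2 against lenti-NC, the camera calls of interferon (0.0745) and ribosomal protein genes (0.0818) did not pass fry. Between the TCF7L2 viruses that of ribosomal protein genes (0.125) did not. In the fit of all 9 libraries the groups share 1 spread per gene. Replicates correlated least within lenti-TCF7L2 (lowest Pearson's r of log2 CPM 0.948, against 0.994 in each other group). The rise from 428 to 3294 when the lenti-TCF7L2 libraries were left out goes with that wider spread. So does the lower adjusted p of Tcf7l2 at an unchanged log2 difference of -0.43. The causes of the other shifts were not tested.

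With each library left out in turn, the counts ran from 2430 to 5481 for lenti-TCF7L2 against lenti-NC, 88 to 2056 for lenti-shTCF7L2 against lenti-NC and 2649 to 5388 between the TCF7L2 viruses. Opposite calls ran from 33 to 493 and same-direction calls from 28 to 737. The log2 difference of Tcf7l2 with lenti-shTCF7L2 ran from -0.52 to -0.37. Car2 stayed short of the threshold under every alternative run, with the lowest adjusted p values at 0.189 and 0.626 against lenti-NC and 0.0824 between the TCF7L2 viruses. DESeq2 was not run for lists, and Tcf7l2 was not tested without the most abundant genes. Car2 had 16 to 41 counts per library.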

Other observations

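All tests of explanations below were chosen only after the result was seen, except that of gene length as the whole cause of the distance of lenti-TCF7L2 replicate 3.

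With lenti-TCF7L2, sarcomere genes were lower (median -0.92) and endothelial markers higher (median 1.71) than with lenti-NC. Fewer reads from long genes in lenti-TCF7L2 replicate 3 do not account for it: without that library the sarcomere median was -0.95 (adjusted p = 6.68e-41) and the endothelial median 1.83. A lower share of cardiomyocytes alone would raise markers of all other heart cell types alike. The endothelial median exceeded that of fibroblast, smooth muscle and epicardial members (0.06) by 1.64 (95% interval 0.90 to 2.22 by bootstrap over genes). That interval treats genes as independent and holds no spread between cultures. Per lenti-TCF7L2 library, the endothelial median lay at least 1.38 above the control mean. The fibroblast, smooth muscle and epicardial medians lay at most 0.26 above it. These values argue against a lower cardiomyocyte share as the only cause. Macrophage and leukocyte markers, not in that comparison, rose too (median 0.76). More endothelial cells in those cultures, an effect of TCF7L2 on endothelial genes, and a difference in virus dose may each contribute and were not tested.

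With lenti-shTCF7L2, interferon response genes had a median of -0.95 against lenti-NC. Fewer leukocytes would be a candidate explanation. The macrophage and leukocyte list, however, had a median of -0.022 (95% interval -0.39 to 0.20 by bootstrap over genes, without spread between cultures). Scaling does not account for the shift either: over 3 other scalings the highest median was -0.93 and the lowest -0.96. The labels give no virus titre, so differences in dose, in vector content or in the response to virus stay open beside an effect of TCF7L2. Shares of cell types other than leukocytes were not tested, and the fibroblast and matrix list was also lower (median -0.18).

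Lenti-TCF7L2 replicate 3 lay 2.66 times as far from replicates 1 and 2 as these lay from each other over 8924 genes. Removing the length trend took away 21.6% of its squared distance and left a ratio of 2.80, so length is unlikely to be the whole cause. The 95% interval of that ratio, 2.71 to 2.89, is a bootstrap over genes and holds no spread between cultures. Its Tcf7l2 level was 2.14 times that of the highest lenti-NC or lenti-shTCF7L2 library (95% counting interval 1.95 to 2.36), which argues against a library of another group under its label. It also had the lowest Tcf7l2 of the 3 lenti-TCF7L2 libraries; RNA quality and a different culture stay open, as the labels give neither.

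For each comparison the 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In each case 1 of the 10 splits, the real one, gave as many genes. The real splits gave 3738, 428 and 3890 genes in lenti-TCF7L2 against lenti-NC, lenti-shTCF7L2 against lenti-NC, and lenti-TCF7L2 against lenti-shTCF7L2. The highest of the other splits gave 0 in edgeR in each, with at most 877, 123 and 642 genes at an unadjusted p under 0.05. Every other split put libraries of both groups on each side, so a difference between the groups counted as spread within sides. Those low counts therefore do not show what unrelated libraries would give.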
